A study of Homo sapiens with 8 samples.

How the data were processed

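RNA was sequenced from AN3CA and KLE, 2 lines of human endometrial cancer cells, with and without Apcin. Apcin is a small molecule that binds CDC20 and blocks its recognition of substrates of the anaphase-promoting complex (APC/C), the ubiquitin ligase that ends mitosis. Per the labels' protocols, cells spent 24 h without serum, a step meant to bring them to rest in G0, and then received complete medium with 10% fetal bovine serum and 0 or 75 µM Apcin for 72 h. AN3CA was kept in MEM and KLE in DMEM/F12, so line and medium differ together. RNA was extracted with Trizol and libraries were made with the TruSeq RNA kit, per the labels' protocols.

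The deposited tables give 1 value per gene and library, and the unit is not named in the labels. The values were taken as FPKM deposited by the authors, because each library sums to between 473619 and 522414 and low values lie in steps that scale with transcript length. Such steps would also arise with other units scaled by length, so the unit stays an assumption. Per the submitters' processing notes, Bowtie2 2.2.5 and RSEM 1.2.12 were used with the genome build GRCh38.p12. The annotation and any filter on genes are not given in the sources used here. Each table lists NCBI gene numbers, 18832 in all, of which 18535 had a symbol in the reference gene names. One table, the second AN3CA control replicate, lists 14855 genes and the other 7 list 18814. The 3977 genes not listed there were set to 0 in that library. Between 4 and 11 of them reached 1 FPKM in the other AN3CA libraries and between 745 and 778 in the KLE libraries. The 18 genes listed only there reached at most 0.11 FPKM.

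The column headers of 2 tables name another sample than the record they are attached to: the record of the second AN3CA Apcin replicate carries the header of the second KLE Apcin replicate, and the reverse. Libraries were assigned by the column header. The assignment by record and a fit without these 2 libraries were run as alternatives. No column of another series' samples was present, and none was used (0 columns). Groups were taken from the labels, with 2 libraries in each of the 4 groups. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

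Sequencing depth is not stated. It was estimated from the steps between low values of genes with a single transcript, with the unit assumed to be FPKM. Of 3343 such genes, 110 to 233 per library entered the fit. The fit scanned 5 to 25 M reads and gave 15.1 to 17.4 M reads per library. Of the values used, 61.3% to 73.3% lay within 0.15 of a whole read. Values did not fall on whole reads closely enough to recover counts (a value was called whole within 0.15 of a read), so no test for counts was run and the count branch of the planned design did not apply.

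Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using a mean-variance trend. The 13204 genes with at least 1 FPKM in at least 2 libraries were tested, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes on this scale understate the change of genes with low values. A fit of the 4 groups over all 8 libraries shared 1 estimate of the spread. It gave the Apcin effect in each line, the difference of these effects (KLE minus AN3CA) and the difference between the control groups. A model with cell line as a covariate gave the common Apcin effect. Calls of both lines were compared with Fisher's exact test, two-sided, beside the overlap of independent lists.

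Gene lists were tested with camera in limma, with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Camera asks whether a list moved relative to the other genes. The question of fry is only whether the list moved at all, which is easily met where many genes change. A list is said to pass where camera at the fixed correlation passed, unless another test is named. Of 39 lists, 38 were tested. They include APC/C subunits, APC/C substrates, mitosis, the spindle checkpoint, DNA replication, homologous recombination, mismatch repair, histones, CDK inhibitors, apoptosis (pro and anti), the integrated stress response, the unfolded protein response, heat shock, proteasome, NRF2, aryl hydrocarbon receptor, interferon, NF-kB, antigen presentation, cholesterol, fatty acids, glycolysis, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, autophagy, immediate early genes, WNT, TGF-beta and matrix, epithelial, mesenchymal and endometrial genes, leukocyte, fibroblast and endothelial markers, and housekeeping genes. The list of mitochondrial genome transcripts matched none of the gene numbers used here and was not analysed here. One tested list, some genes and a comparison with leukocyte markers are not reported here. Groups, tests, lists, most other settings and the rule for named genes were fixed before the data were examined.

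Genes were named by rule: 15 fixed genes of the APC/C, cell cycle and apoptosis; the 10 largest rises and 10 largest falls past the threshold within each line; the 5 largest in each direction for the other comparisons; and up to 2 called members per list and direction. The largest changes needed a mean of at least 2 FPKM and both libraries of one group on the same side of both libraries of the other. Genes without a symbol, pseudogenes by symbol and genes that would show sex were left out. Gene positions are those of the GRCh38 reference annotation, 1-based.

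The pipeline was tested on simulated data built from the real group means and spread, with 200 genes changed. In the AN3CA comparison 56.7% of genes changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold were recovered, and in the KLE comparison 67.2%, 94% and 98.5%. The changed genes were drawn only from those above the filter level in controls, with folds set on the log2(FPKM + 1) scale. Recovery of genes near 1 FPKM was therefore not measured. False calls numbered 8 (4.6% of calls) and 16 (8.5%). A shifted list was found and none of the other lists was called. The simulated noise was drawn separately for each gene. It therefore cannot show how often lists whose genes vary together are called falsely. Results were recomputed with quantile and upper-quartile scaling, other filters and pseudocounts, a fit without trend, a fold threshold, fits on fewer libraries, a replicate block and each library left out in turn. Lists were also recomputed after a spline correction of each library for transcript length or GC content. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.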

Results

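The series holds 8 RNA-seq libraries of AN3CA and KLE, 2 cell lines from human endometrial carcinoma, with 2 libraries in each of 4 groups: AN3CA control, AN3CA with 75 µM Apcin for 72 h, KLE control and KLE with 75 µM Apcin for 72 h. Values above 0 were listed for 14410 and 14845 genes in the AN3CA controls, 15086 and 15110 with Apcin, 16797 and 16667 in the KLE controls and 17101 and 17018 with Apcin. Estimated depth lay between 15.1 and 17.4 M reads per library. Across genes, log2 values correlated at r = 0.9756 to 0.9982 between libraries of the same line (12 pairs) and at 0.827 to 0.839 between lines (16 pairs). The SD of the log2 difference between the 2 libraries of a group was 0.222 in AN3CA controls, 0.157 in AN3CA with Apcin, 0.235 in KLE controls and 0.142 in KLE with Apcin. Libraries were assigned by column header, which for 2 tables differs from the record. Assigned by record, limma called 0 genes in each of the 5 comparisons, with 1729 genes at an unadjusted p under 0.05 for AN3CA, 111 for KLE, 1111 for their difference, 706 for the common effect and 3547 between the controls.

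The first question was what Apcin changed in AN3CA. ATF3, a stress-induced transcription factor, rose from 2.46 ± 0.382 to 67.5 ± 1.97 FPKM (SD, n = 2 per group). Its log2 change was 4.31 (SE 0.14, limma adjusted p = 2.77e-07). DDIT3, which encodes the stress transcription factor CHOP, rose from 18.3 ± 1.22 to 230.0 ± 3.30 FPKM. Its log2 change was 3.58 (SE 0.09, adjusted p = 7.37e-08). HSPA8, which encodes the constitutive heat shock cognate chaperone, fell from 1441 ± 135 to 249.5 ± 1.03 FPKM (log2 -2.52, SE 0.10, adjusted p = 4.03e-07). UHRF1, which links DNA methylation to replication, fell from 37.3 ± 1.16 to 8.77 ± 0.396 FPKM (log2 -1.97, SE 0.10, adjusted p = 1.10e-06). On GRCh38, the protein coding genes ATF3 (NCBI gene 467), DDIT3 (1649), HSPA8 (3312) and UHRF1 (29128) lie on chromosome 1 at 212565334 to 212620777, chromosome 12 at 57516588 to 57521737, chromosome 11 at 123057489 to 123063230 and chromosome 19 at 4903080 to 4962154. In all, 7032 of 13204 genes (53.3%) passed the limma test. Of these 4263 were higher and 2769 lower with Apcin, and 662 rose and 361 fell by at least 2-fold. Quantile scaling moved the share of higher calls from 60.6% to 49.4%, and without the 2 libraries of differing header 4629 genes were called.

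Genes of the integrated stress response, the programme that ATF4 drives when translation initiation is limited, rose almost as a whole in AN3CA: 32 of 33 rose and none fell (33 and 0 adjusted over the list alone). Their median log2 change was 2.16 (camera adjusted p = 7.15e-18, and adjusted p = 0.295 with an estimated correlation). NUPR1, a stress-induced chromatin protein, rose from 20.6 ± 3.68 to 349.9 ± 17.1 FPKM (log2 4.03, SE 0.22). TRIB3, a pseudokinase induced by ATF4 and CHOP, rose from 10.8 ± 0.714 to 179 ± 10.6 FPKM (log2 3.94, SE 0.24). SESN2, an inhibitor of growth signalling, rose from 8.81 ± 0.757 to 129 ± 4.20 FPKM (log2 3.73, SE 0.14). Of 25 chaperone and sensor genes of the unfolded protein response, 12 rose and 8 fell (the same numbers adjusted over the list alone), and the list did not pass camera (adjusted p = 0.578), though it passed fry (2.25e-05). ERN1, which encodes the sensor IRE1, rose by 2.32 log2 units (SE 0.10). CRELD2 and MANF, secreted proteins of the endoplasmic reticulum, fell by 1.29 (SE 0.11) and 0.90 (SE 0.12). Among 33 autophagy and lysosome genes 18 rose and 2 fell (18 and 2 adjusted over the list alone; median 0.22, camera adjusted p = 0.0109, and adjusted p = 0.342 with an estimated correlation). WIPI1, which acts in autophagosome formation, rose by 2.69 (SE 0.09), and GLA, a lysosomal galactosidase, fell by 0.72 (SE 0.07). Immediate early genes counted 15 rises and 3 falls among 24 (16 and 5 adjusted over the list alone; median 0.74, camera adjusted p = 0.0104, and adjusted p = 0.295 with an estimated correlation). JUN rose from 4.01 ± 0.516 to 52.2 ± 1.34 FPKM (log2 3.41, SE 0.09). DUSP6, a phosphatase of ERK, fell from 152 ± 6.26 to 67.8 ± 1.51 FPKM (log2 -1.15, SE 0.11).

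In AN3CA CDKN1A, which encodes the CDK inhibitor p21, rose from 9.27 ± 0.396 to 68.1 ± 0.339 FPKM (log2 2.75, SE 0.13, limma adjusted p = 7.29e-07). GDF15, a secreted stress cytokine, rose from 75.2 ± 7.12 to 906 ± 70.7 FPKM (log2 3.58, SE 0.22). MDM2, a ubiquitin ligase gene, rose by 1.11 (SE 0.12) and PHLDA3 fell by 0.82 (SE 0.11). Of 26 CDK inhibitor and cell cycle exit genes, 14 rose and 3 fell (16 and 3 adjusted over the list alone; median 0.48, camera adjusted p = 0.024, and adjusted p = 0.306 with an estimated correlation), a call that ended with a minimum mean of 5 FPKM (0.125) and with the 4 AN3CA libraries alone (0.0635). KLF4 rose by 2.14 (SE 0.11) and CDKN2C, which encodes p18, fell by 0.97 (SE 0.10). Neither apoptosis list passed camera: 9 of 36 pro-apoptotic genes rose and 7 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.993). Of the anti-apoptotic genes 8 of 15 rose and 4 fell (8 and 4; adjusted p = 0.472). With fry, which asks only whether a list moved at all, both passed (adjusted p = 0.0184 and 0.00124). Single members moved further. BBC3, which encodes PUMA, rose from 0.980 ± 0.410 to 8.89 ± 0.764 FPKM (log2 2.33, SE 0.15). The death receptor gene TNFRSF10B rose by 1.81 (SE 0.09), PMAIP1, which encodes NOXA, rose by 1.08 (SE 0.14) and CASP2 fell by 0.87 (SE 0.08). MCL1 and BCL2, survival genes, rose by 0.78 (SE 0.07) and 0.53 (SE 0.11), the latter not past the threshold with quantile scaling (adjusted p = 0.0509). BIRC5, which encodes survivin, fell by 0.23 (SE 0.07, adjusted p = 0.0235), but not without AN3CA control replicate 2 (0.0663) or Apcin replicate 1 (0.153). BCL2L11, which encodes BIM, fell by 0.37 (SE 0.10, adjusted p = 0.0136), but not without the same libraries (0.0648 and 0.08).

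Replication genes fell together in AN3CA: 46 of 50 genes of DNA replication and the G1/S transition fell and none rose (46 and 0 adjusted over the list alone). The median was -0.77 (camera adjusted p = 5.50e-20, and adjusted p = 0.265 with an estimated correlation). MCM4, a subunit of the replicative helicase, fell from 50.2 ± 2.66 to 15.4 ± 0.948 FPKM (log2 -1.64, SE 0.09). PCNA, the sliding clamp of DNA polymerases, fell from 157 ± 12.5 to 62.1 ± 0.948 FPKM (log2 -1.32, SE 0.08). Homologous recombination and damage response genes counted 12 falls and 4 rises among 33 (camera adjusted p = 0.0116, and adjusted p = 0.525 with an estimated correlation). CLSPN, a checkpoint adaptor, fell by 1.49 (SE 0.15). That list missed the threshold without AN3CA Apcin replicate 2 (adjusted p = 0.0590) and without the 2 libraries of differing header (0.0549). Of 9 mismatch repair genes, 3 rose and 4 fell (camera adjusted p = 0.256, fry 0.0349).

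Transcripts of APC/C substrates and mitotic genes, which bear on the pathway Apcin acts on, were mostly lower or unmoved in AN3CA. These lists share genes, among them CCNB1, PTTG1 and NEK2, so their calls are not separate evidence. The substrate list also shares CDC6, TK1 and RRM2 with the replication list. Among 30 substrates 14 fell and 4 rose (14 and 4 adjusted over the list alone; median -0.20, camera adjusted p = 0.00239, and adjusted p = 0.265 with an estimated correlation). Among 53 mitotic genes 18 fell and 9 rose (18 and 9 adjusted over the list alone; median -0.12, camera adjusted p = 0.00731, and adjusted p = 0.295 with an estimated correlation). CCNB1, which encodes cyclin B1, fell from 186 ± 9.96 to 121 ± 5.67 FPKM (log2 -0.62, SE 0.07). PTTG1, which encodes securin, fell from 271 ± 8.63 to 187 ± 5.74 FPKM (log2 -0.54, SE 0.07). The proliferation marker MKI67 fell from 72.3 ± 1.96 to 45.0 ± 2.89 FPKM (log2 -0.67, SE 0.08). NEK2, a centrosomal kinase, rose by 0.60 (SE 0.08) and CKS1B rose by 0.72 (SE 0.08). CDC20, the protein Apcin binds, stood at 153 ± 1.41 FPKM in controls and 127 ± 10.5 with Apcin (log2 -0.27, SE 0.11, limma adjusted p = 0.064). It passed with upper-quartile scaling (0.0169), with a minimum mean of 5 FPKM (0.0496) and without KLE control replicate 1 or 2 (0.0233 and 0.0232). UBE2C, an E2 enzyme of the APC/C, stood at 193 ± 7.52 and 169 ± 11.6 FPKM (log2 -0.20, SE 0.09, adjusted p = 0.083, and 0.0199 with upper-quartile scaling). FZR1, the other APC/C activator, stood at 18.1 ± 0.976 and 17.3 ± 2.10 FPKM (log2 -0.07, SE 0.12, adjusted p = 0.695). Of 21 APC/C subunits and regulators, 7 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.993, with a median of 0.03 and a test direction of lower). ANAPC16 rose by 0.79 (SE 0.08) and ANAPC5 fell by 0.64 (SE 0.10). The spindle checkpoint and kinetochore list had 6 rises and 11 falls among 28 (camera adjusted p = 0.11, fry 0.0325). After a correction of each library for GC content it passed, with a median of -0.352 (adjusted p = 0.00679) where it was -0.094 before. The median of the mitotic list was then -0.287 and that of the substrates -0.345. Replication-dependent histones had 4 rises and 4 falls among 19 (3 and 4 adjusted over the list alone; adjusted p = 0.685).

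Some lists of metabolism and protein upkeep passed camera as lower in AN3CA. Of 24 cholesterol synthesis genes 20 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -0.97 (camera adjusted p = 1.20e-09, and adjusted p = 0.295 with an estimated correlation). STARD4, a sterol carrier, rose by 0.91 (SE 0.20). Fatty acid genes had 9 falls and 2 rises among 20 (camera adjusted p = 0.0222, and adjusted p = 0.525 with an estimated correlation). FASN, fatty acid synthase, had a log2 change of -1.56 (SE 0.17). The list missed the threshold with quantile scaling (adjusted p = 0.0559) and with fry (0.0714). Of 21 heat shock genes 16 fell and 4 rose (16 and 4 adjusted over the list alone; median -0.75, camera adjusted p = 1.10e-05, and adjusted p = 0.295 with an estimated correlation). HSPB1, a small heat shock protein, fell from 501 ± 9.25 to 103 ± 14.1 FPKM (log2 -2.28, SE 0.10). The transcription factor gene HSF2 rose by 0.84 (SE 0.10). HSPA1B fell by 2.29 (SE 0.19), with reads that may be shared with its near-identical copy HSPA1A. Of 41 nuclear genes of oxidative phosphorylation 22 fell and 2 rose (camera adjusted p = 1.14e-05, and adjusted p = 0.295 with an estimated correlation). Of 31 proteasome subunits 13 fell and 4 rose (camera adjusted p = 0.00468, and adjusted p = 0.383 with an estimated correlation). Of 32 ribosome biogenesis genes 15 fell and 5 rose (camera adjusted p = 0.00178, and adjusted p = 0.295 with an estimated correlation). NDUFB10, a complex I subunit, fell by 1.81 (SE 0.16). PSMB6, a proteasome core subunit, fell by 1.14 (SE 0.10). The proteasome list missed the threshold with quantile scaling (adjusted p = 0.246). Beside 10000 random lists of the same control level, the median of the proteasome list (-0.154) lay at percentile 78.25 and that of oxidative phosphorylation (-0.322) at 17.07. After a correction for GC content these medians were -0.346 (adjusted p = 1.53e-04) and -0.422 (6.86e-06). Of 77 cytosolic ribosomal proteins 39 fell and none rose (median -0.33, camera adjusted p = 4.28e-08, and adjusted p = 0.383 with an estimated correlation). The test direction turned with quantile scaling (adjusted p = 0.483). RPL23 fell from 1462 ± 206 to 765 ± 7.88 FPKM (log2 -0.93, SE 0.11). Ribosomal protein genes share sequence with many pseudogenes and their values are uncertain. Random lists of the same control level had a lower median than these 77 genes.

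Other lists in AN3CA divided as follows. Antigen presentation genes had 10 falls and 1 rise among 20 (camera adjusted p = 0.0175, and adjusted p = 0.385 with an estimated correlation). PSME1, a proteasome activator subunit, fell by 1.04 (SE 0.07). That call ended with quantile scaling (adjusted p = 0.0516), without AN3CA control replicate 1 (0.0569) and after a correction for GC content (0.132, median -0.230 before and -0.203 after). Not past camera were interferon-stimulated genes (12 rises and 7 falls among 41, 12 and 6 adjusted over the list alone, adjusted p = 0.809), NF-kB and secretory genes (6 and 3 among 27, 0.963), and NRF2 genes (12 and 9 among 26, 0.909). The same held for aryl hydrocarbon receptor targets (0 and 0 among 8, 0.993), glycolysis and hypoxia genes (9 and 14 among 31, 0.105), WNT targets (0 and 4 among 12, 0.0862, but 0.0340 with a minimum mean of 5 FPKM, 0.0487 with a pseudocount of 0.1 and 0.0250 with the 4 AN3CA libraries alone) and TGF-beta and matrix genes (8 and 10 among 32, 0.256). Of the lineage lists, none passed camera either: epithelial genes (4 and 0 among 22, 0.666), mesenchymal genes (2 and 4 among 20, 0.0948), endometrial lineage genes (3 and 7 among 15, 0.158) and housekeeping genes (3 and 8 among 16, 0.0778). Markers of other cell types did not pass camera either: leukocyte (0 and 1 among 4, 0.212), fibroblast (1 and 2 among 9, 0.159) and endothelial (0 and 0 among 6, 0.909). With fry the epithelial (adjusted p = 0.0349), mesenchymal (0.0023), endometrial (0.00412), housekeeping (1.77e-04), leukocyte (0.00438) and fibroblast (0.00412) lists passed. So did those of NF-kB (0.00731), NRF2 (0.0306), glycolysis (0.0485) and WNT (0.00119). Since 53.3% of all tested genes were called in AN3CA, passing fry does not set these lists apart from other genes. SLC7A11, the cystine transporter of the NRF2 list, rose from 3.60 ± 0.693 to 42.9 ± 8.23 FPKM (log2 3.25, SE 0.26). The largest rises also held AKNA, a microtubule organiser, from 2.19 ± 0.339 to 43.3 ± 0.997 FPKM (log2 3.80, SE 0.10). The largest fall was that of P2RY6, a nucleotide receptor, from 30.7 ± 2.0 to 2.29 ± 0.0640 FPKM (log2 -3.27, SE 0.15). TMT1B fell from 32.7 ± 0.481 to 2.71 ± 0.0210 FPKM (log2 -3.18, SE 0.11). S100A4, a calcium-binding protein of the mesenchymal list, fell by 2.32 (SE 0.15). SULT1A4 (log2 -2.59, SE 0.66), which has near-identical copies, was past the threshold at 0.00827 but not without AN3CA control replicate 2 (0.0657) or Apcin replicate 2 (0.0697).

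**Figure D1:**
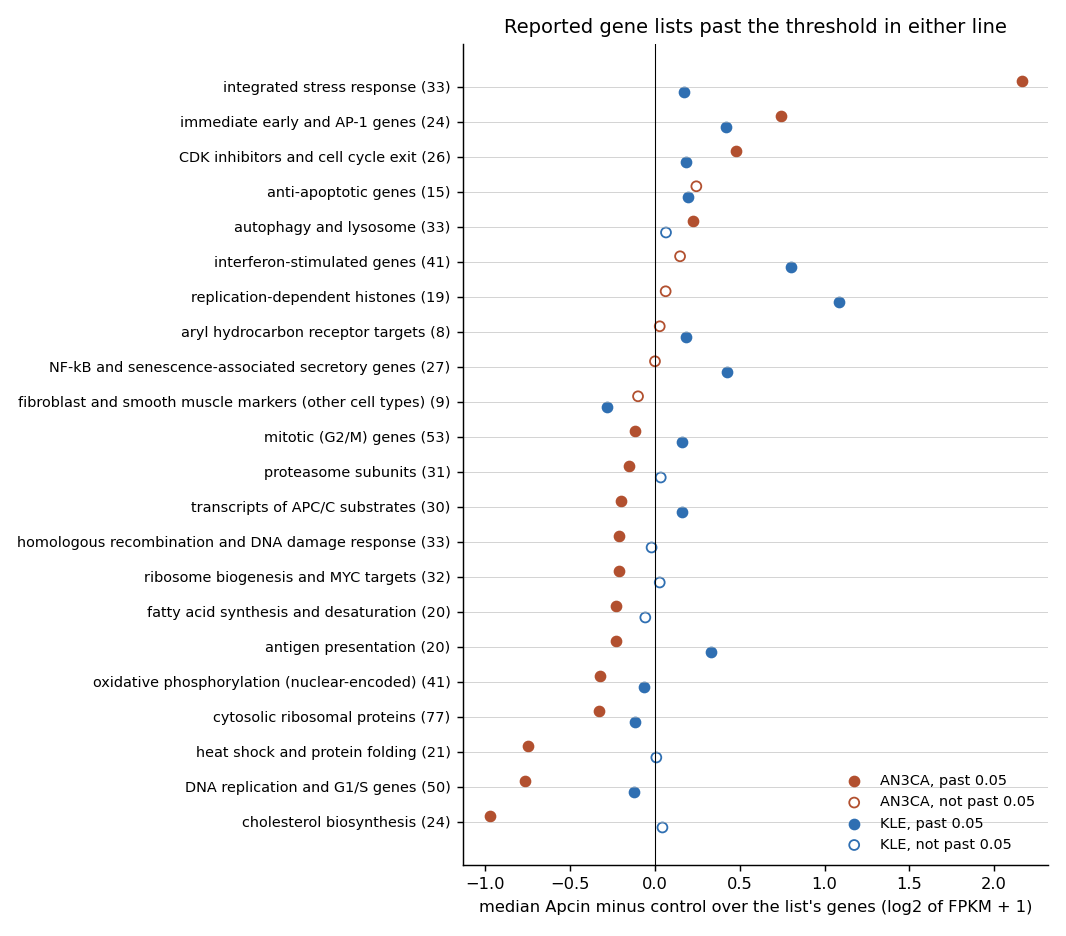
Median Apcin minus control difference (horizontal axis, log2 of FPKM + 1) of gene lists past the threshold in either line, with the number of tested genes in brackets. Red-brown points are AN3CA and blue points KLE, filled where camera passed 0.05, and they show the integrated stress response at 2.16 in AN3CA and 0.17 in KLE and histones at 1.09 in KLE.

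In KLE fewer genes passed with the same treatment than in AN3CA. CXCL3, a neutrophil-attracting chemokine, rose from 1.15 ± 0.170 to 11.98 ± 0.389 FPKM (n = 2 per group, log2 2.60, SE 0.10, limma adjusted p = 5.83e-06). Its relative CXCL2 rose by 2.54 (SE 0.13, adjusted p = 2.45e-05). H2BC8, a histone H2B gene, rose from 5.75 ± 1.27 to 35.6 ± 4.98 FPKM (log2 2.44, SE 0.16, adjusted p = 1.22e-04). OAS2, an antiviral sensor of double-stranded RNA, rose from 8.57 ± 2.23 to 29.4 ± 4.81 FPKM (log2 1.68, SE 0.18, adjusted p = 0.00157). AGR2, a disulfide isomerase of secretory epithelium, fell from 17.9 ± 1.06 to 6.11 ± 1.11 FPKM (log2 -1.42, SE 0.12, adjusted p = 5.72e-04). CXCL3 (NCBI gene 2921), CXCL2 (2920), H2BC8 (8339) and OAS2 (4939) are protein coding genes on GRCh38 chromosome 4 at 74036589 to 74038807 and 74097035 to 74099293, chromosome 6 at 26215159 to 26216692 and chromosome 12 at 112978395 to 113011723. CXCL2 and CXCL3 were listed at 0 in AN3CA, except that control replicate 2 does not list them and they were set to 0 there. In all, 513 of 13204 genes (3.9%) passed in KLE. Of these 351 were higher and 162 lower, with 82 and 10 of them changed at least 2-fold. Without the 2 libraries of differing header 36 genes were called. The count was 147 without KLE Apcin replicate 1, 170 without KLE Apcin replicate 2 and 891 without KLE control replicate 1. The share of higher calls moved from 68.4% to 55.3% with quantile scaling, 56.6% with upper-quartile scaling and 82.9% with a pseudocount of 0.1.

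Interferon-stimulated genes rose in KLE in 33 of 41 cases with no fall (39 and 0 adjusted over the list alone; median 0.80, camera adjusted p = 4.95e-33, and adjusted p = 0.164 with an estimated correlation). MX1, an antiviral GTPase, stood at 47.0 ± 17.9 and 129 ± 23.4 FPKM (log2 1.48, SE 0.23, adjusted p = 0.00777). It was not past the threshold without KLE Apcin replicate 1 (0.13) or 2 (0.0513). Of 20 antigen presentation genes 8 rose and none fell (11 and 0 adjusted over the list alone; camera adjusted p = 1.96e-07, and adjusted p = 0.176 with an estimated correlation). TAP1, a peptide transporter, rose by 0.86 (SE 0.10). Of 19 replication-dependent histones 13 rose and none fell (17 and 0 adjusted over the list alone; median 1.09, camera adjusted p = 3.79e-17, and adjusted p = 0.0258 with an estimated correlation). H3C4, a histone H3 gene, rose by 1.76 (SE 0.20). Histone genes are near-identical copies, so values of single members are uncertain. NF-kB and secretory genes had 12 rises and no fall among 27 (16 and 1 adjusted over the list alone; median 0.42, camera adjusted p = 2.42e-09, and adjusted p = 0.0307 with an estimated correlation). Immediate early genes had 11 rises and no fall among 24 (15 and 0 adjusted over the list alone; median 0.42, camera adjusted p = 3.82e-12, and adjusted p = 0.0307 with an estimated correlation). JUNB rose from 11.5 ± 4.63 to 41.1 ± 0.778 FPKM (log2 1.80, SE 0.20). ATF3 rose from 5.30 ± 1.17 to 22.2 ± 2.54 FPKM (log2 1.89, SE 0.14, adjusted p = 2.63e-04). Histones, NF-kB and immediate early genes were the only lists past the threshold in KLE with an estimated correlation.

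Some stress and cell cycle lists passed camera in KLE. CDKN1A rose from 4.20 ± 0.997 to 10.6 ± 0.877 FPKM (log2 1.17, SE 0.13, limma adjusted p = 0.00159). CDK inhibitors had 3 rises among 26 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00256, and adjusted p = 0.18 with an estimated correlation). KLF4 rose by 1.03 (SE 0.11). Integrated stress response genes had 3 rises among 33 (10 and 2 adjusted over the list alone; median 0.17, camera adjusted p = 0.0107, and adjusted p = 0.692 with an estimated correlation). PPP1R15A, a phosphatase subunit that reverses the response, rose by 1.13 (SE 0.13). That list missed the threshold with fry (0.181) and without KLE Apcin replicate 1 (adjusted p = 0.0967) and turned direction without KLE control replicate 2 (0.846). Of 53 mitotic genes 6 rose and none fell (19 and 2 adjusted over the list alone; median 0.16, camera adjusted p = 1.90e-04, and adjusted p = 0.164 with an estimated correlation). Of 30 APC/C substrates, some of them also mitotic list members, 4 rose and none fell (9 and 0 adjusted over the list alone; median 0.16, camera adjusted p = 0.0134, and adjusted p = 0.164 with an estimated correlation). The substrate list missed the threshold without KLE control replicate 1 (0.0853), KLE Apcin replicate 2 (0.0637) or the 2 libraries of differing header (0.0820). CCNB1 rose from 141 ± 0.530 to 185 ± 0.247 FPKM (log2 0.39, SE 0.07, adjusted p = 0.0197), but not past the threshold without KLE control replicate 2 (0.0698) or Apcin replicate 1 (0.178) or 2 (0.177). PTTG1 rose by 0.38 (SE 0.07, adjusted p = 0.0191), but not without the same 3 libraries (0.0765, 0.19 and 0.163). CDC20 stood at 228 ± 35.8 and 291 ± 11.5 FPKM (log2 0.36, SE 0.11, adjusted p = 0.11), past the threshold without KLE control replicate 2 (0.0402). UBE2C stood at 1.53 ± 0.0490 and 1.85 ± 0.141 FPKM (adjusted p = 0.334), FZR1 at 8.64 ± 1.15 and 8.95 ± 0.339 FPKM (0.858) and MKI67 at 42.7 ± 1.73 and 44.7 ± 2.65 FPKM (0.739).

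Apoptosis genes in KLE gave 2 rises and no fall among 36 pro-apoptotic members (camera adjusted p = 0.487). There were 2 rises and no fall among 15 anti-apoptotic members (7 and 0 adjusted over the list alone; camera adjusted p = 0.00676, and adjusted p = 0.164 with an estimated correlation). BIRC3, an inhibitor of apoptosis induced by NF-kB, rose by 0.84 (SE 0.11, limma adjusted p = 0.0038). PMAIP1 rose by 0.83 (SE 0.14, adjusted p = 0.00937), but not without KLE control replicate 2 (0.0592) or Apcin replicate 1 (0.138) or 2 (0.0803). GDF15 rose from 1.39 ± 0.863 to 4.95 ± 1.22 FPKM (log2 1.35, SE 0.22, adjusted p = 0.00967), but not without KLE Apcin replicate 1 (0.144). BBC3 (log2 0.75, SE 0.15, adjusted p = 0.0305) and BIRC5 (log2 0.34, SE 0.07, adjusted p = 0.0359) lost their calls without any 1 of 6 libraries, namely both Apcin replicates of AN3CA and all 4 KLE libraries. Adjusted p was then from 0.0544 to 0.234 for BBC3 and from 0.0583 to 0.264 for BIRC5. MDM2 (log2 0.13, SE 0.12, adjusted p = 0.607), MCL1 (0.14, SE 0.07, 0.365), BCL2 (0.09, SE 0.11, 0.726) and BCL2L11 (0.18, SE 0.10, 0.38) did not pass.

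Some lists were lower in KLE with no single member past the threshold. One was DNA replication (0 of 50 fell, also adjusted over the list alone; median -0.12, camera adjusted p = 2.39e-06, and adjusted p = 0.245 with an estimated correlation). Others were ribosomal proteins (0 of 77, median -0.12, 9.74e-09, and adjusted p = 0.473 with an estimated correlation) and oxidative phosphorylation genes (0 of 41, median -0.07, 0.0045, and adjusted p = 0.44 with an estimated correlation). None of these 3 passed fry (0.0943, 0.253 and 0.279). The last missed the threshold with quantile scaling (0.0617) and without KLE Apcin replicate 1 (0.0540). Fibroblast and smooth muscle markers fell in 3 of 9 cases (3 adjusted over the list alone; median -0.28, camera adjusted p = 0.00469, and adjusted p = 0.164 with an estimated correlation). The list missed the threshold with a minimum mean of 5 FPKM (0.0799), without the filter (0.0501) and over genes listed in all tables (0.125). LUM, a matrix proteoglycan listed or set at 0 in AN3CA, fell from 9.71 ± 0.389 to 5.80 ± 0.573 FPKM (log2 -0.66, SE 0.10, limma adjusted p = 0.00722), and not past the threshold without KLE Apcin replicate 2 (0.0666). Aryl hydrocarbon receptor targets rose in 3 of 8 cases (4 and 1 adjusted over the list alone; camera adjusted p = 0.0247, and adjusted p = 0.18 with an estimated correlation). CYP1A1, a xenobiotic-oxidising enzyme, rose from 1.06 ± 0.361 to 4.42 ± 0.544 FPKM (log2 1.40, SE 0.13). That list missed the threshold without KLE control replicate 1 (0.0896) or Apcin replicate 2 (0.0530), without the filter on low values (0.436) and with a minimum mean of 5 FPKM (0.326).

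The remaining lists did not pass camera in KLE: APC/C subunits (0 rises, 0 falls among 21, adjusted p = 0.603), spindle checkpoint (0 and 0 among 28, 0.71), homologous recombination (0 and 0 among 33, 0.183), and mismatch repair (0 and 0 among 9, 0.122). Nor did unfolded protein response (0 and 0 among 25, 0.99), heat shock (0 and 0 among 21, 0.821), proteasome (0 and 0 among 31, 0.71), NRF2 (2 and 0 among 26, 7 and 0 adjusted over the list alone, 0.0509). The NRF2 list passed in 10 other settings. These were quantile scaling (0.0128), a minimum mean of 5 FPKM (0.0424), pseudocounts of 0.1 (0.0466) and 0.5 (0.0482), the replicate block (0.0427) and genes listed in all tables (0.0423). It also passed without AN3CA control replicate 1 (0.0454) or 2 (0.0454), KLE control replicate 1 (0.0051) or KLE Apcin replicate 1 (0.0197). Without KLE control replicate 1, homologous recombination (0.0263) and mismatch repair (0.0337) passed too. Metabolic lists did not pass camera with all libraries: cholesterol (0 and 0 among 24, 0.603), fatty acids (0 and 1 among 20, 0.108), glycolysis (0 and 0 among 31, 0.183), ribosome biogenesis (1 and 0 among 32, 0.664) and autophagy (0 and 0 among 33, 0.278). Without KLE control replicate 1 cholesterol (0.00237) and fatty acids (0.0279) passed with their direction reversed, and without KLE control replicate 2 they passed at 1.66e-07 and 2.05e-10. Signalling and lineage lists did not pass camera: WNT (3 and 0 among 12, 0.0738, but 9.19e-04 with a minimum mean of 5 FPKM), TGF-beta and matrix (2 and 4 among 32, 0.456), epithelial (2 and 2 among 22, 0.664), mesenchymal (2 and 0 among 20, 0.71), endometrial lineage (0 and 0 among 15, 0.747) and housekeeping genes (1 and 0 among 16, 0.664). HMOX1, heme oxygenase 1, rose from 7.85 ± 0.453 to 15.9 ± 2.52 FPKM (log2 0.92, SE 0.10). CCN1 and CCN2, matricellular proteins induced by YAP and TGF-beta, moved apart: CCN1 rose by 0.82 (SE 0.09) and CCN2 fell from 683 ± 39.9 to 411 ± 11.4 FPKM (log2 -0.73, SE 0.07). Keratin genes also moved apart, with KRT7 higher by 0.77 (SE 0.10) and KRT4, listed or set at 0 in AN3CA, lower by a log2 of -1.21 (SE 0.11). ATP6V1B1, a proton pump subunit, had the largest named fall, from 13.3 ± 1.25 to 4.07 ± 0.955 FPKM (log2 -1.51, SE 0.13). Leukocyte markers (1 rise, 0 falls among 4, camera adjusted p = 0.603) and endothelial markers (0 and 1 among 6, 0.288, but 0.0274 over genes listed in all tables) did not pass camera. With fry unfolded protein response (0.0283), WNT (0.00584), leukocyte (0.0184) and endothelial lists (0.0286) passed in KLE. HBA1, a globin of red cells listed or set at 0 in AN3CA, rose from 1.83 ± 0.304 to 4.49 ± 0.290 FPKM (log2 0.95, SE 0.11), and TIE1, an endothelial receptor, fell by 0.83 (SE 0.09).

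**Figure D2:**
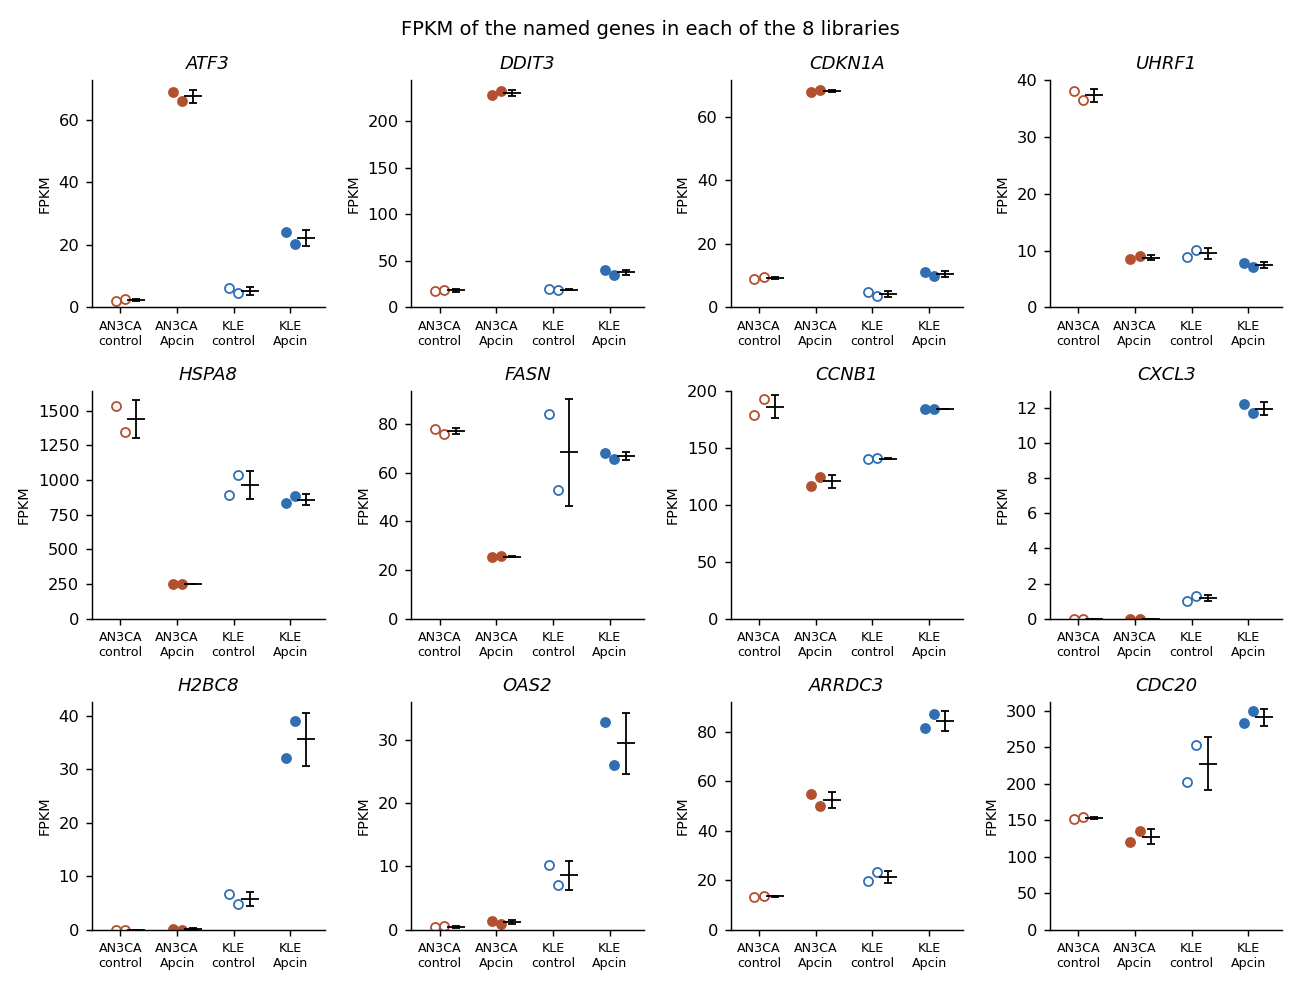
FPKM (vertical axes from 0, a scale per gene) of named genes in each library of the 4 groups, with open circles for controls, filled circles for Apcin and black bars for the group mean ± SD (n = 2). ATF3 rises in both lines, to 67.5 FPKM in AN3CA and 22.2 in KLE, while CXCL3 is listed or set at 0 in AN3CA and reaches 11.98 in KLE.

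Whether the Apcin effect differed between the lines was tested on the difference itself. The integrated stress response was the group that differed most: all 33 genes had a lower effect in KLE than in AN3CA (33 adjusted over the list alone, median -1.99, camera adjusted p = 1.73e-20, and adjusted p = 0.182 with an estimated correlation). NUPR1 differed by a log2 of -3.31 (SE 0.32, limma adjusted p = 1.19e-04), SESN2 by -3.30 (SE 0.20) and AKNA by -3.90 (SE 0.15). In the other direction, HSPB1 stood at 184 ± 13.2 and 209 ± 4.15 FPKM in KLE, a difference of effects of 2.47 (SE 0.14). IFIT1, an antiviral RNA-binding protein, went from 13.9 ± 2.04 to 4.56 ± 0.0420 FPKM in AN3CA and from 10.0 ± 2.26 to 25.5 ± 4.79 FPKM in KLE. Its difference was 2.69 (SE 0.23, adjusted p = 8.16e-05). The difference passed for 5146 of 13204 genes, 2238 higher and 2908 lower in KLE relative to AN3CA, and for 1615 without the 2 libraries of differing header. The count was 3301 without KLE Apcin replicate 2.

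DNA replication genes had a higher effect in KLE than in AN3CA, with 36 of 50 differing upward and none downward (39 and 0 adjusted over the list alone; median 0.69, camera adjusted p = 5.34e-16, and adjusted p = 0.154 with an estimated correlation). Cholesterol genes had 19 higher and 1 lower among 24 (20 and 1 adjusted over the list alone; median 0.99, 6.07e-09, and adjusted p = 0.298 with an estimated correlation). Heat shock genes had 15 and 2 among 21 (15 and 2 adjusted over the list alone; median 0.68, 9.22e-06, and adjusted p = 0.279 with an estimated correlation). Interferon-stimulated genes had 26 and 1 among 41 (27 and 1 adjusted over the list alone; median 0.62, 1.74e-08, and adjusted p = 0.369 with an estimated correlation). Histones had 14 and 0 among 19 (15 and 0 adjusted over the list alone; median 1.11, 5.57e-06, and adjusted p = 0.109 with an estimated correlation). APC/C substrates differed upward in 14 of 30 cases with none downward (14 and 0 adjusted over the list alone; median 0.29, 9.22e-06, and adjusted p = 0.109 with an estimated correlation). Mitotic genes differed upward in 21 of 53 with 3 downward (22 and 3 adjusted over the list alone; median 0.21, 3.05e-05, and adjusted p = 0.154 with an estimated correlation). The substrate and mitotic lists share genes. After a correction for GC content the mitotic median was 0.381 (1.11e-07), and 0.302 (2.04e-05) after one for length. CCNB1, lower in AN3CA and higher in KLE, differed by 1.01 (SE 0.10, limma adjusted p = 1.65e-04). CDC20 differed by 0.63 (SE 0.15, adjusted p = 0.0108), but not without KLE Apcin replicate 2 (0.0609). Antigen presentation (11 and 0 among 20, 1.40e-05), ribosome biogenesis (14 and 3 among 32, 6.76e-04) and NF-kB (13 and 4 among 27, 8.13e-04) differed upward. So did oxidative phosphorylation (12 and 2 among 41, 0.00161), ribosomal proteins (13 and 2 among 77, 0.00161), proteasome (13 and 3 among 31, 0.00358) and WNT genes (5 and 0 among 12, 0.0114). In AN3CA the medians of the first 3 lay at percentiles 17.07, 99.97 and 78.25 of random lists of the same control level. Such lists were not drawn for the difference, so these 3 differences may not be particular to the lists. Autophagy genes differed downward (1 and 14 among 33, 0.0184). With an estimated correlation their adjusted p ranged from 0.154 to 0.631. The ribosomal list did not pass fry (0.209) and its direction turned with quantile scaling (adjusted p = 0.0936), the autophagy call ended without AN3CA control replicate 2 (0.0560) or the 2 libraries of differing header (0.0687) and the oxidative phosphorylation and proteasome calls with quantile scaling (0.142 each). Also lost were the WNT call without the filter on low values (0.111) and the NF-kB call over genes listed in all tables (0.115).

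Across genes, which are not independent replicates, the log2 effects of the lines correlated at r = 0.202, and 52.8% of the genes called in KLE had the same sign in AN3CA. Genes at 0 in all AN3CA libraries have no sign there and were counted with the rest, so the rest are not all opposite. Genes higher in both lines numbered 122, against 113.3 for independent lists (Fisher's exact test, p = 0.325), and genes lower in both numbered 28, against 34 (exact p = 0.285). These 150 shared calls ranged from 30 to 293 with 1 library left out, and were 8 without the 2 libraries of differing header. Only 10 genes were higher in AN3CA and lower in KLE, against 52.3 for independent lists (exact p = 7.08e-16), and 40 were lower in AN3CA and higher in KLE, against 73.6 (exact p = 2.81e-06). These tests take in all tested genes, among them genes absent from 1 line that could not be called there. The expected numbers are therefore only a rough guide. ARRDC3, an arrestin-domain protein that directs receptor turnover, was among those higher in both: it rose from 13.4 ± 0.184 to 52.4 ± 3.37 FPKM in AN3CA and from 21.3 ± 2.57 to 84.2 ± 3.95 FPKM in KLE. Its difference between lines was 0.05 (limma adjusted p = 0.802).

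**Figure D3:**
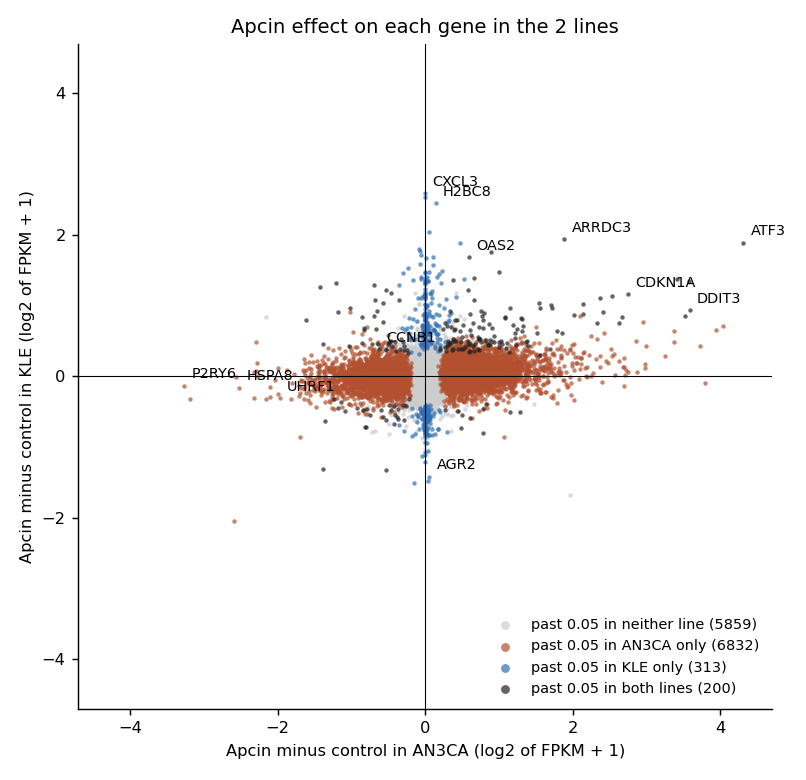
Each point is 1 of 13204 genes, with its Apcin minus control difference in AN3CA on the horizontal axis and in KLE on the vertical axis (log2 of FPKM + 1). Colours give the line in which limma passed 0.05, and ARRDC3 lies near the diagonal while ATF3 lies further along the AN3CA axis.

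The common effect, fitted with cell line as a covariate, included ARRDC3 with a log2 change of 1.91 (SE 0.08, n = 4 per arm, limma adjusted p = 6.97e-05), higher with Apcin in 4 of 4 libraries. IER3, an early response gene of the NF-kB list, rose from 116 ± 26.6 to 257 ± 4.84 FPKM in AN3CA and from 102 ± 2.67 to 199 ± 4.55 FPKM in KLE. Its common change was 1.06 (SE 0.11, adjusted p = 0.0178). It was not past the threshold without AN3CA control replicate 1 (0.0536), AN3CA Apcin replicate 1 or 2 (0.0922 and 0.0871), KLE control replicate 2 (0.0626) or KLE Apcin replicate 1 (0.0817). ATF3 had a common change of 3.10 (SE 0.43, adjusted p = 0.0337), and lost its call without AN3CA control replicate 1 or 2 (0.125 and 0.119), AN3CA Apcin replicate 1 or 2 (0.124 and 0.122), KLE control replicate 2 (0.0757) or KLE Apcin replicate 1 (0.0838). In all 117 genes passed, 98 higher and 19 lower. The count was 1 to 1871 with 1 library left out, the latter without KLE control replicate 1, and 22 without the filter on low values. Quantile scaling moved the share of higher calls from 83.8% to 61.8% and upper-quartile scaling to 72.0%.

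Among lists, immediate early genes had 7 rises and no fall among 24 in the common effect (17 and 1 adjusted over the list alone; median 0.71, camera adjusted p = 9.43e-06, and adjusted p = 0.121 with an estimated correlation). Interferon-stimulated genes had 6 and 0 among 41 (22 and 0 adjusted over the list alone; median 0.50, 8.82e-08, and adjusted p = 0.497 with an estimated correlation). Integrated stress response genes had 2 and 0 among 33 (27 and 0 adjusted over the list alone; median 1.14, 1.59e-08, and adjusted p = 0.497 with an estimated correlation). DNA replication genes were lower as a list with none of 50 past the threshold over all genes (0 and 38 adjusted over the list alone; median -0.46, 8.91e-18, and adjusted p = 0.497 with an estimated correlation). With fry the last 3 did not pass (0.0759, 0.106 and 0.0784). Across the comparisons, 17 of 38 lists passed in AN3CA, 16 in KLE, 17 for the difference, 17 for the common effect and 15 between the controls, and 0, 3, 0, 0 and 0 with an estimated correlation.

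Without Apcin the lines differed in identity genes. KRT8, an epithelial keratin, stood at 1.65 ± 0.983 FPKM in AN3CA and 3985 ± 103 in KLE (n = 2 per group, log2 10.61, SE 0.19, limma adjusted p = 5.31e-11). MEST, an imprinted hydrolase gene, stood at 6771 ± 369 FPKM in AN3CA and 0.880 ± 1.0 in KLE (log2 -11.92, SE 0.28, adjusted p = 2.97e-10). COL1A2, a collagen I chain, stood at 457 ± 12.7 and 0.05 ± 0.0570 FPKM (log2 -8.77, SE 0.08). UBE2C was at 193 ± 7.52 FPKM in AN3CA and 1.53 ± 0.0490 in KLE (log2 -6.26, SE 0.09, adjusted p = 1.27e-11). KRT8 (NCBI gene 3856) and UBE2C (11065) lie on GRCh38 chromosome 12 at 52897187 to 52949954 and chromosome 20 at 45812576 to 45816957. In all, 10483 of 13204 genes (79.4%) differed. Of these 4816 were higher and 5667 lower in KLE, with 2595 and 2181 by at least 2-fold. The culture medium differs with the line.

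Epithelial genes were higher in KLE in 21 of 22 cases and lower in 1 (the same numbers adjusted over the list alone; median 4.85, camera adjusted p = 1.24e-09, and adjusted p = 0.289 with an estimated correlation). Mesenchymal genes also were higher in 14 of 20 cases and lower in 6 (14 and 6 adjusted over the list alone; median 1.64, camera adjusted p = 0.0293, and adjusted p = 0.324 with an estimated correlation), a call that ended with a minimum mean of 5 FPKM (0.251) and over genes listed in all tables (0.0561). CDH2, N-cadherin, stood at 0.0750 ± 0.0350 FPKM in AN3CA and 100.1 ± 1.60 in KLE. ZEB1, a repressor of epithelial genes, stood at 31.4 ± 0.516 and 2.58 ± 0.559 FPKM. Interferon-stimulated genes were higher in KLE in 37 of 41 cases and lower in 4 (median 1.94, camera adjusted p = 6.78e-08, and adjusted p = 0.434 with an estimated correlation). IFI27 stood at 0.580 ± 0.0990 and 129.7 ± 18.1 FPKM and BST2 in the other direction at 107 ± 10.9 and 14.3 ± 2.13 FPKM. NF-kB genes were higher in 24 of 27 cases and lower in 1 (median 1.47, 6.98e-07, and adjusted p = 0.139 with an estimated correlation). CCL2, a monocyte chemokine, stood at 0.105 ± 0.148 and 139 ± 20.4 FPKM. Antigen presentation genes had 13 higher and 2 lower of 20 (0.00673, and adjusted p = 0.425 with an estimated correlation). TGF-beta and matrix genes (24 higher, 7 lower of 32, 0.00147), histones (15 and 1 of 19, 0.0132) and aryl hydrocarbon receptor targets (6 and 1 of 8, 0.0485) were higher in KLE, with adjusted p from 0.289 to 0.332 with an estimated correlation. Lower in KLE were DNA replication genes (41 lower, 3 higher of 50, median -0.78, 1.24e-04, and adjusted p = 0.402 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, stood at 115 ± 5.52 and 28.6 ± 0.820 FPKM. Ribosomal proteins (57 and 5 of 77, 9.91e-04), homologous recombination (21 and 2 of 33, 0.0293), autophagy (22 and 7 of 33, 0.0401), unfolded protein response (16 and 4 of 25, 0.0485) and NRF2 genes (16 and 5 of 26, 0.0485) also were lower, with adjusted p from 0.332 to 0.619 with an estimated correlation. Homologous recombination lost its call with quantile scaling (0.0805), a minimum mean of 5 FPKM (0.0957) and over genes listed in all tables (0.0592), and autophagy in the same settings (0.126, 0.0896 and 0.0781). Unfolded protein response genes lost theirs in 10 settings besides the estimated correlation (0.0510 to 0.127), and NRF2 (0.0510 to 0.107) and aryl hydrocarbon receptor targets (0.0510 to 0.320) in 9 each. Without KLE control replicate 2 the first 2 stood at 0.0637 and 0.0691. Between the controls 11 to 16 lists passed with 1 library left out, 9 with quantile scaling and 8 with a minimum mean of 5 FPKM. Endometrial lineage genes divided, 6 higher and 7 lower of 15 (camera adjusted p = 0.913, fry 2.52e-05): the Mullerian transcription factor PAX8 stood at 0.0250 ± 0.0350 FPKM in AN3CA and 75.9 ± 1.46 in KLE, and PAX2 at 17.2 ± 1.51 and 0.0250 ± 0.0350 FPKM.

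Chromosome 19 carried the window with the highest median difference between the control groups, a region singled out after its values were seen. All 55 tested genes between 38000001 and 40000000 (GRCh38) were higher in KLE and past the threshold, with a median log2 difference of 2.712. SPINT2, a membrane protease inhibitor, stood at 0.515 ± 0.276 FPKM in AN3CA and 1641 ± 8.46 in KLE, and C19orf33 at 0.1 ± 0.141 and 1025 ± 93.1 FPKM. In the same window were the ribosomal protein gene RPS16 at 715 ± 108 and 5688 ± 433 FPKM, the proteasome gene PSMD8 at 185 ± 10.2 and 1401 ± 20 FPKM and FBL, fibrillarin, at 353 ± 8.10 and 2262 ± 189 FPKM.

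**Figure D4:**
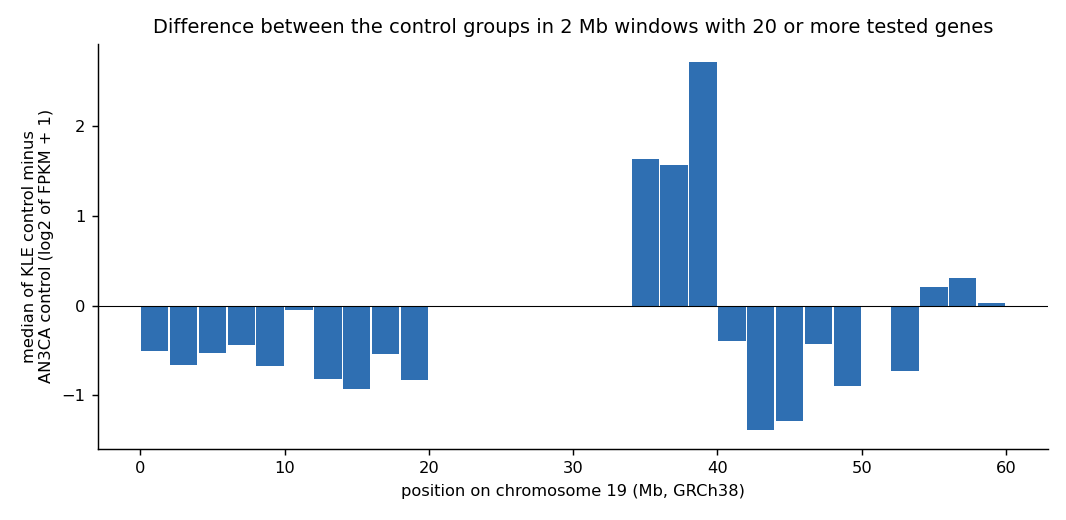
Median difference between KLE and AN3CA controls (vertical axis, log2 of FPKM + 1) over the tested genes of each 2 Mb window of chromosome 19 with 20 or more such genes (horizontal axis, Mb on GRCh38). The bar at 38 to 40 Mb reaches 2.712 over 55 genes, next to 1.633 and 1.565 in the windows before it.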

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

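The tests of replicate noise, of column headers, of length and GC content and of a single library were chosen only after the result was seen. Each result listed here was picked out because the Apcin effect differed between KLE and AN3CA by the limma test of the difference itself, with Benjamini-Hochberg adjustment. The difference passed for 5146 genes and for 17 gene lists, and for 0 lists with an estimated correlation. The gene count was 3301 without KLE Apcin replicate 2 and 1615 without the 2 libraries of differing header. Values are log2 differences, KLE effect minus AN3CA effect. Medians of the lists reported here were -1.99 for the integrated stress response and -0.24 for autophagy, and on the other side 1.11 for histones, 0.99 for cholesterol, 0.69 for DNA replication, 0.68 for heat shock, 0.62 for interferon-stimulated genes, 0.57 for NF-kB genes, 0.52 for antigen presentation, 0.44 for WNT targets, 0.29 for APC/C substrates, 0.29 for ribosome biogenesis, 0.21 for mitotic genes, 0.21 for ribosomal proteins, 0.19 for oxidative phosphorylation and 0.19 for the proteasome. The falls of ribosomal proteins, oxidative phosphorylation and the proteasome in AN3CA were not set apart from random lists of the same control level.

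Of 80 genes named for the Apcin effects, 70 passed the test of the difference and 10 did not. Many were named for a large change in 1 line or for this same difference, so a high share was built in. Of all 13204 tested genes 39% passed. A higher effect in KLE than in AN3CA was found for P2RY6 3.14, TMT1B 2.87, IFIT1 2.69, CXCL3 2.60, CXCL2 2.54, HSPB1 2.47, HSPA8 2.36, HSPA1B 2.35, H2BC8 2.30, S100A4 2.01, JUNB 1.88, NDUFB10 1.72, UHRF1 1.67, FASN 1.56, TAP1 1.56, MCM4 1.46, CYP1A1 1.38, PSMB6 1.31, CLSPN 1.29 and CRELD2 1.25. Smaller differences of the same sign were found for PCNA 1.19, PSME1 1.19, DUSP6 1.11, OAS2 1.08, CCNB1 1.01, MANF 1.0, HBA1 0.95, PTTG1 0.91, H3C4 0.86, BIRC3 0.82, CDKN2C 0.82, CASP2 0.79, KRT7 0.74, MKI67 0.73, RPL23 0.69, GLA 0.68, ANAPC5 0.64, CDC20 0.63, BIRC5 0.57, BCL2L11 0.55 and UBE2C 0.36. With all libraries and the main settings, the Apcin effect on CDC20 and UBE2C passed in neither line. UBE2C had low values in KLE, where this scale understates changes.

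A lower effect in KLE than in AN3CA was found for AKNA -3.90, NUPR1 -3.31, SESN2 -3.30, TRIB3 -3.28, SLC7A11 -2.96, DDIT3 -2.64, WIPI1 -2.55, ATF3 -2.42, GDF15 -2.23, ERN1 -2.07, JUN -2.03, TNFRSF10B -1.69, BBC3 -1.58, CDKN1A -1.58, AGR2 -1.47, PPP1R15A -1.41, ATP6V1B1 -1.36, CCN2 -1.21, KRT4 -1.21, KLF4 -1.11, STARD4 -1.0, MDM2 -0.99, TIE1 -0.92, CKS1B -0.85, ANAPC16 -0.79, HSF2 -0.68, LUM -0.66, MCL1 -0.64 and CCN1 -0.48. CXCL2, CXCL3, KRT4, LUM and HBA1 were listed at 0 in AN3CA or, in control replicate 2, not listed and set to 0, so for them the difference is the KLE change alone.

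The larger response of AN3CA was weighed against noisier KLE replicates. The SD across genes of the log2 change that both replicate pairs share was 0.551 or 0.557 in AN3CA and 0.192 or 0.195 in KLE, depending on the pairing, and the higher ratio of KLE to AN3CA was 0.351. Noise alone cannot lower this shared part, so that explanation was excluded as the whole cause. The design had largely settled this before the test. The fit used 1 spread for both lines, with a median SE of 0.106 in each. The SD of the log2 difference between replicates was 0.235 and 0.142 in KLE groups, and 0.222 and 0.157 in AN3CA groups. Column headers that name the wrong line were also excluded: the 2 libraries concerned correlated with libraries of the line in their header at 0.9777 or more, and with the other line at 0.839 or less. A biological difference between the lines in their response may remain, as a hypothesis, but medium and line differ together and no dose or time course was analysed here.

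The fall of ribosomal protein transcripts in AN3CA was weighed against length, GC content and scaling. After a correction of each library for transcript length the list passed at an adjusted p of 2.75e-07, with a median of -0.39, and after a correction for GC content at 2.81e-07, with a median of -0.32. Uncorrected, the list had an adjusted p of 0.383 with an estimated correlation, and its direction turned with quantile scaling (0.483). A first run with the longest transcript of each gene gave 1.52e-05 and 4.75e-07. It was replaced because the longest transcripts include ones with retained introns (median length 1857 nt for these genes, against 644 nt for the coding transcript used). The median of the list lay at percentile 99.97 of 10000 random lists matched on control level, whose median was -0.64. Other abundant transcripts thus fell by more, and the fall was not particular to ribosomal proteins. A single scaling factor per library would move all genes in the same direction. The median over all tested genes was 0.055 in AN3CA, which argues against such a factor as the whole cause. A shift confined to abundant transcripts stays open. At that level the random lists drew on a limited pool of genes. In KLE the median of the ribosomal list, -0.115, lay at percentile 0 of such lists, whose median was -0.048.

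The rise of interferon-stimulated genes in KLE was weighed against a single library. The highest adjusted p of the list with 1 of the 8 libraries left out was 3.41e-23 at the fixed correlation, which excludes a single library as the whole cause. With an estimated correlation and all libraries the list did not pass (adjusted p = 0.164). A response of KLE cells to Apcin may explain the rise, as a hypothesis, but the stimulus was not tested.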

How the results depend on the processing

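The tests by record, without the 2 libraries of differing header, with crossed numbers, on genes listed in all tables and after the length and GC corrections were chosen only after the result was seen. With 1 library left out, limma calls ranged from 5405 to 7352 in AN3CA (7032 with all), 147 to 891 in KLE (513), 3301 to 5132 for the difference (5146), 1 to 1871 for the common effect (117) and 10038 to 10336 between controls (10483). The lone library of such a group was assumed to vary like the other groups. Lists past camera ranged from 16 to 17, 14 to 19, 16 to 20, 15 to 18 and 11 to 16 in the same order, and genes called in the same direction in both lines from 30 to 293 (150 with all). Without the 2 libraries of differing header the counts were 4629 in AN3CA, 36 in KLE, 1615 for the difference, 1 for the common effect and 8 shared. With libraries assigned by record all 5 comparisons had 0. A log2 change of at least 1 left 1023, 92, 995, 27 and 4776 in the order above, and 12 shared. In KLE the count was 314 with a minimum mean of 5 FPKM, 222 with a pseudocount of 0.1, 287 over genes listed in all tables and 139 with the 4 KLE libraries alone. The common effect had 22 without the filter and 6249 as the mean of the within-line contrasts, which leave the difference between lines out of the residual spread. Shared calls were 87 without the filter, 89 with a pseudocount of 0.1 and 36 when each line was fitted alone. Replicate numbers recur in every group but mark nothing shared in the labels: deviations of same-numbered libraries correlated at -0.192 in AN3CA and -0.034 in KLE. With the number as a replicate block, calls were 259 in KLE, 1 for the common effect and 59 shared, and with crossed pairing 1 for the common effect. With an estimated correlation 0, 3, 0, 0 and 0 lists passed, and with fry 31 in AN3CA, 26 for the difference, 5 for the common effect and 34 between controls. Between controls 9 lists passed with quantile scaling, 8 with a minimum mean of 5 FPKM and 8 over genes listed in all tables. Outside the length and GC corrections, the direction of lists past the threshold with or without the change of setting turned in 5 cases: ribosomal proteins with quantile scaling in AN3CA (adjusted p = 0.483) and for the difference (0.0936), and in KLE the integrated stress response without control replicate 2 (0.846), and, without control replicate 1, cholesterol (0.00237) and fatty acids (0.0279). Over the 8 left-out libraries the adjusted p of these 3 lists in KLE ranged from 1.22e-06 to 0.846, 1.66e-07 to 0.859 and 2.05e-10 to 0.192. After a correction for GC content the spindle checkpoint list passed in AN3CA (0.00679) and for the difference (0.00477), recombination passed for the difference (0.00222) and antigen presentation no longer passed in AN3CA (0.132). After one for transcript length NRF2 passed in KLE (0.0496) and recombination for the difference (0.0434). The fold threshold lowers counts by its construction; the cause of the other changes was not tested. Upper-quartile scaling moved the median difference between controls by 0.121. No called gene of the text changed sign in the settings fitted gene by gene, which leave out the assignment by record, crossed numbers and the length and GC corrections. Fits for counts were not run, since no counts were given, and the estimated depth of 15.1 to 17.4 M reads limits what can be said of genes near 1 FPKM.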

Other observations

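The tests in this part were chosen only after the result was seen, except the splits of the 8 libraries. Beyond the genes above, some other genes that differed between the control groups were picked out. SLPI, a secreted protease inhibitor, stood at 0.0700 ± 0.0990 FPKM in AN3CA and 1511 ± 29.1 in KLE (SD, n = 2), and IGFBP7, a secreted growth factor binding protein, at 0.0950 ± 0.134 and 299.9 ± 33.6 FPKM. MGP, a matrix protein that inhibits calcification, stood at 3216 ± 489.6 FPKM in AN3CA and 0.445 ± 0.530 in KLE, and AKR1C1, a ketosteroid reductase, at 345 ± 5.90 and 0.0750 ± 0.106 FPKM. Of transcription factors, WT1 stood at 0.0700 ± 0.0990 and 56.4 ± 5.20 FPKM, and GATA2 at 40.9 ± 2.81 and 1.65 ± 0.757 FPKM. FN1, fibronectin, stood at 9.60 ± 0.629 and 544 ± 4.14 FPKM.

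Of 163 windows of 2 Mb with at least 20 tested genes, the one on chromosome 19 from 38 to 40 Mb had the highest median, 2.712, against a highest of 1.629 in 1000 shuffles of gene positions (permutation p = 0.001, the smallest that 1000 shuffles give). Windows of at least 10 genes were looked at first. The 10 tested genes nearest UBE2C had a median log2 difference of 0.57, KLE minus AN3CA controls, against -6.26 for UBE2C, so the low value of UBE2C in KLE was not shared by its neighbours. Among the 34 splits of the libraries into 4 and 4 that could be fitted with cell line as a covariate, 1 called at least as many genes as the real one, which was the real split itself (117 calls), and the highest of the others called 3. In the other splits much of the Apcin effect stays in the residual spread, which lowers their calls, so this contrast was largely set beforehand. With 1 library left out the count of the real split fell to as few as 1.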
